A study of Mus musculus with 4 samples.

How the data were processed

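Gene expression was measured on 4 one-colour Affymetrix arrays, each hybridised with biotin-labelled total RNA of small intestinal epithelial cells from mice of the C57BL/6J strain. Per the labels' protocols, the animals were 10 weeks old, healthy and kept under specific pathogen-free conditions, and the epithelium was loosened from the dissected intestine with EDTA and collected by hand under a stereomicroscope. The labels placed 2 arrays in a group heterozygous for the AP-1B gene and 2 in a knockout group. Replicates were numbered 1 and 2 within each group, and the labels do not say whether a number marks a shared litter, day or batch, nor whether each array came from a separate animal, so the p-values measure only the spread between these samples, which may be technical.

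The deposited table held 1 intensity value per probe set and array on a linear scale. Per the submitters' processing notes the values came from MAS5, whose version was not given in the sources used here. The array medians lay between 0.996 and 0.998, so each array had been rescaled to a median near 1, a step that is seen in the values and not stated in the labels. Values therefore read as multiples of the array median. The table had 45037 probe sets and no control probe sets. The 75th percentile was 4.13 and 4.27 on the arrays labelled heterozygous 1 and knockout 2, and 5.54 and 5.57 on those labelled heterozygous 2 and knockout 1. No detection calls, scanner files or scan dates were used here, and the number of arrays limits the precision. No pair of arrays had identical values at more than 0.144% of probe sets, so all 4 were counted as separate samples.

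Probe sets were named from the platform annotation paired with the table. It gave 1 gene for 34945 probe sets, several for 932 and none for 9160. Names were checked against a RefSeq gene table of assembly GRCm38.p6, in which the Entrez identifiers of 34741 of the 1-gene probe sets were found, and 0 symbols needed an update. No gene was named from a probe set with several. No coordinates are given, since the build behind the annotation is not stated.

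Values were transformed as log2(value + 0.32), where the pseudocount is the 25th percentile of all values. Fold differences on this scale understate those of dim probe sets. Probe sets were kept when their mean over the 4 arrays reached the median of such means, 0.983, which left 22519, of which 19642 were named for 1 gene. No further scaling was applied to the main comparison. The 2 groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. An exact permutation test of 2 against 2 arrays cannot go below p = 0.333 (two-sided) and was not used. A descriptive tier, called candidates here, took probe sets with an unadjusted p under 0.01, a difference of at least 2-fold and groups that did not overlap. Log2 differences are given as knockout minus heterozygous, by label.

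For gene lists, 11326 genes were each represented by the kept 1-gene probe set with the highest mean. Of 35 lists, 34 were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, with an estimated correlation and fry as alternatives, and the list of sex-linked transcripts served as a check of the samples. Genes next to Ap1m2 were the 50 protein-coding genes on each side in the order of the RefSeq table.

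The genes named were set by rule. These were every probe set of Ap1m2, then up to 12 genes in each direction past the adjusted threshold with groups that did not overlap, filled where fewer passed with candidates in order of p. Each list added up to 4 members past the threshold or, where fewer than 2 passed, the 2 with the smallest p as values. Lists of other cell types and of sex-linked transcripts added their 2 brightest members, and Pigr, Reg3b and Reg3g were always given. Genes named outside the rule are said to be so. Groups, tests, lists, naming rule and the settings to vary were fixed before the data were examined. The settings varied were other pseudocounts, filters and scalings, fits without the trend or with a robust one, the replicate number as a block, each array left out in turn, a threshold of 0.10, other set tests, the mean of a gene's probe sets and 20 neighbours on each side. A block of crossed pairs and 3 settings of the list test were added after the data were seen.

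The fit was tested on simulated data with 200 changed among 22519 probe sets, in 10 data sets per setting. For the comparison of 2 heterozygous with 2 knockout arrays, independent arrays with the fitted spread gave back 3.62% of 2-fold, 44.9% of 4-fold and 92.7% of 8-fold changes, with 13.5 unchanged probe sets called per data set. With the residuals of the real arrays kept in place, 0% of 2-fold, 0.147% of 4-fold and 19.5% of 8-fold changes were called. Those residuals were centred within each label, so unchanged probe sets had no group difference and 0 of them were called. That setting thus keeps the spread within labels but not chance differences between them. With the smaller spread seen between the arrays labelled heterozygous 1 and knockout 2, the shares were 30.1%, 99.7% and 100%, so the sensitivity depends on the spread assumed. Figures were drawn with matplotlib 3.10.9.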

Results

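Epithelial cells of the small intestine were profiled to compare mice lacking AP-1B with heterozygous mice of the same strain. AP-1B is the epithelial form of the AP-1 clathrin adaptor, which sorts membrane proteins to the basolateral surface, and Ap1m2 encodes its mu1B subunit. The data were 4 arrays of 45037 probe sets, 2 labelled heterozygous and 2 labelled knockout, with values given as multiples of the array median. No wild-type array was analysed here, so the heterozygous arrays were the control. Arrays are named by label and replicate number.

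The targeted gene was examined first, as a check of the labels. Ap1m2, measured by 1 probe set (1460190_at), had a signal of 19.9 on the array labelled heterozygous 1, 4.33 on heterozygous 2, 2.49 on knockout 1 and 22.3 on knockout 2. The mean was 12.1 ± 10.99 (SD, n = 2) for the arrays labelled heterozygous and 12.4 ± 13.97 (SD, n = 2) for those labelled knockout, a log2 difference of −0.28 with a standard error of 0.89 (limma, adjusted p = 0.999907). The array labelled knockout 2 thus had 5.14 times the Ap1m2 signal of heterozygous 2 and 8.95 times that of knockout 1. The array labelled heterozygous 1 had 7.99 times the signal of knockout 1 and 4.59 times that of heterozygous 2. Among kept probe sets, 1.14% differed more between the heterozygous arrays and 0.826% between the knockout arrays. The Ap1m2 signal therefore went against the labels of heterozygous 2 and knockout 2, and every direction given here follows the labels. The labels do not say which part of the gene was removed, and a probe set outside that part would not check them.

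**Figure D1:**
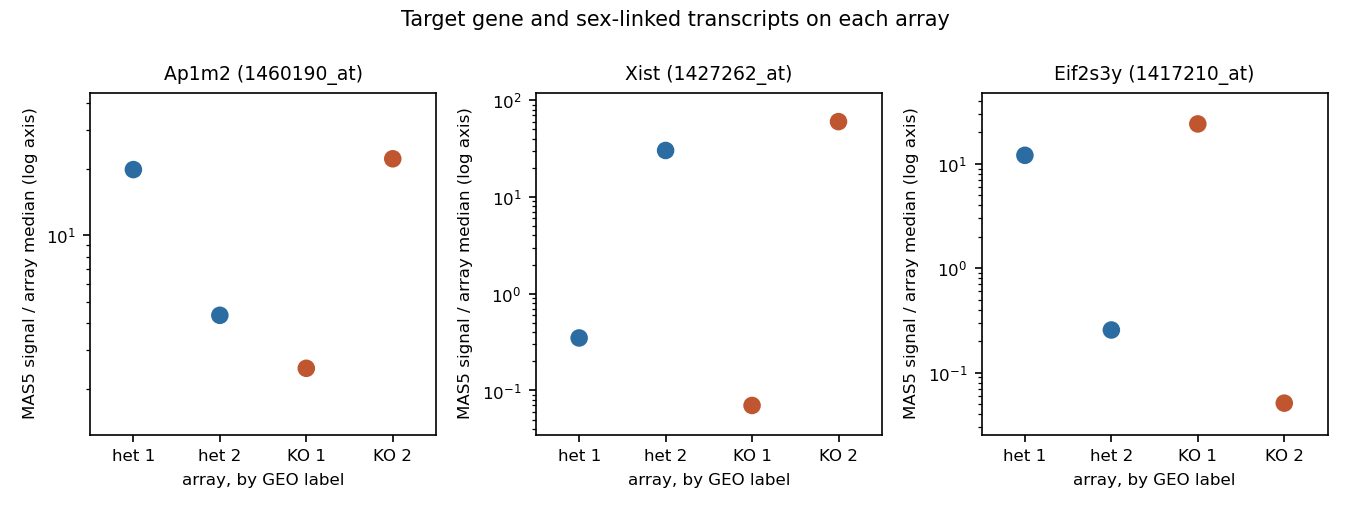
Signal of Ap1m2, Xist and Eif2s3y on each array (points, 1 per array, coloured by label) as a multiple of the array median on a log axis. Ap1m2 was 19.9 and 22.3 on heterozygous 1 and knockout 2 and 4.33 and 2.49 on heterozygous 2 and knockout 1, while Xist was high on both replicate 2 arrays and Eif2s3y on both replicate 1 arrays.

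The whole arrays followed the division of Ap1m2 in part. Over kept probe sets, the arrays labelled heterozygous 1 and knockout 2 were the most alike, with 740 probe sets 2-fold or more apart, while heterozygous 2 lay about as far from knockout 1 (2151) as from knockout 2 (2509), with 1860 and 1699 after quantile normalization. The heterozygous arrays differed from each other at 3066 probe sets and the knockout arrays at 5316, while heterozygous 1 and knockout 1 differed at 5725. Xist, the transcript that silences an X chromosome in female cells, had signals of 0.349, 30.3, 0.070 and 60.1 on heterozygous 1, heterozygous 2, knockout 1 and knockout 2. The Y-linked Eif2s3y had 12.1, 0.256, 24.1 and 0.051, Kdm5d had 4.88, 0.602, 5.39 and 0.159, and Uty had 3.75, 0.335, 4.45 and 0.037, in the same order. Both replicate 1 arrays thus had the male and both replicate 2 arrays the female pattern, so that each label held 1 of either sex.

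Between the labelled groups, in which the Ap1m2 signal of 2 arrays went against the label, no probe set passed the adjusted threshold by limma. With the spread of these arrays within labels kept, and no chance difference between the groups, the fit gave back 0.147% of simulated 4-fold and 19.5% of 8-fold changes. A lack of calls therefore does not show a lack of change. Among candidates, none of which passed the adjusted threshold, Pck1, the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, had the lowest log2 difference, −2.77 with a standard error of 0.81, from 37.2 ± 7.58 on the arrays labelled heterozygous to 8.31 ± 9.48 on those labelled knockout (SD, n = 2 each). Other candidates with lower values on both arrays labelled knockout were Cytip, a cytohesin-binding protein of lymphocytes (log2 difference −2.01), Ubxn11 (−1.90), the matrix protein gene Sparc (−1.90), the mast cell protease gene Mcpt1 (−1.81), the transcription factor gene Batf (−1.74) and Gucy1b1, a subunit of soluble guanylate cyclase (−1.56). Cyp2d10 (−1.50), the Wnt inhibitor gene Apcdd1 (−1.45), the ectonucleotidase gene Enpp3 (−1.42) and Vegfa (−1.39) completed the 11 named candidates with lower values. The 8 named candidates with higher values were Mettl1, a tRNA methyltransferase (2.15), Nolc1, a nucleolar phosphoprotein (2.06), Ppp1r3e (2.02), Pou5f2 (1.92), the endocytic scaffold gene Itsn1 (1.91), Sycn, a protein of pancreatic secretory granules (1.86), Ercc2, a helicase of DNA repair (1.69), and Sh3pxd2b (1.57). With each array left out in turn, all 19 kept their sign, which groups that do not overlap fix in advance. Of the 19, 14 stayed within 1.5 times of the value given, which choosing by a small p also favours. The exceptions were Pck1 (−1.28 without knockout 1, −4.27 without knockout 2), Cytip (−1.01) and Batf (−0.96) without knockout 1, Nolc1 (0.90 without heterozygous 1, 3.22 without heterozygous 2) and Sycn (2.82 and 0.90 in the same order).

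Most of these were dim, with a mean near or below the array median in 1 of the labelled groups. Mettl1 went from 0.803 ± 0.301 to 5.01 ± 3.003 and Sparc from 1.75 ± 0.198 to 0.235 ± 0.0445, by label, and Enpp3 from 4.30 ± 1.27 to 1.39 ± 0.351 (SD, n = 2 each). All 4 kept probe sets of Enpp3 and all 3 of Mettl1, Nolc1, Sparc and Cytip lay on the same side, 4 of 5 did for Itsn1 and 1 of 2 for Sh3pxd2b. For Sparc and Sycn the candidate was not the gene's brightest probe set, which had an unadjusted p of at least 0.05 by limma.

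**Figure D2:**
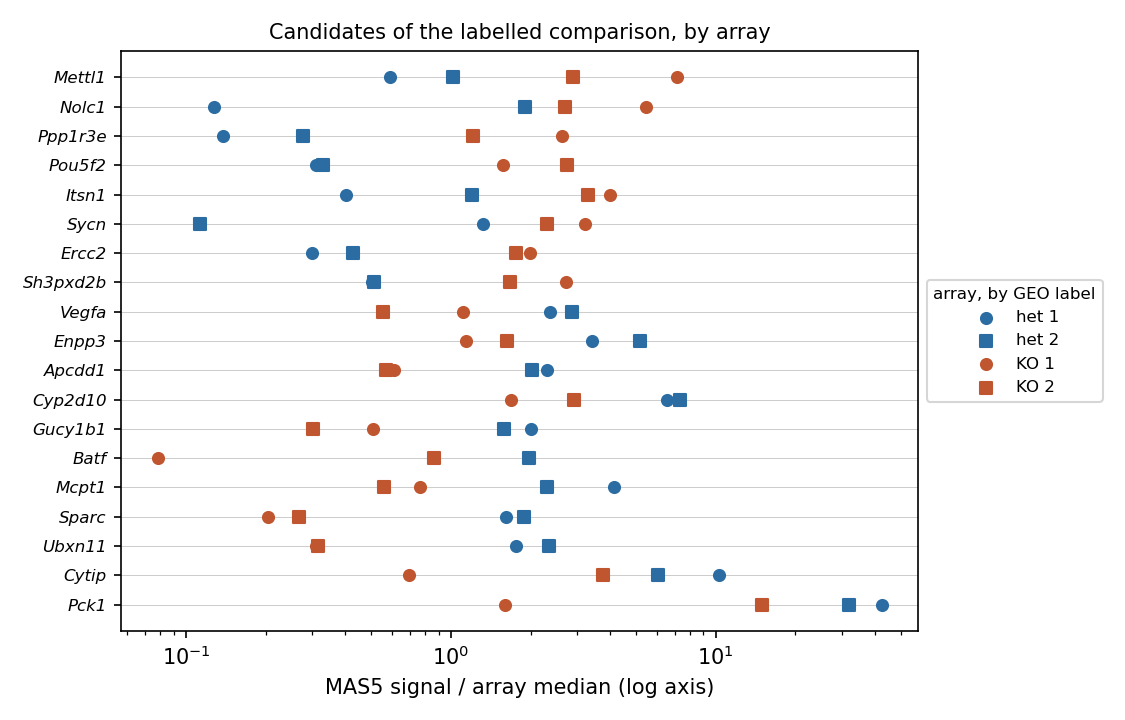
Signal of the 19 named candidates on each array as a multiple of the array median (log axis; blue, labelled heterozygous; orange, labelled knockout; circles, replicate 1; squares, replicate 2). The groups do not overlap for any of them, which the rule requires, and Pck1 spans 1.61 and 15.0 on the arrays labelled knockout against 42.6 and 31.9 on those labelled heterozygous.

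By limma with Benjamini-Hochberg adjustment, 0 probe sets were higher and 0 lower, with a lowest adjusted p of 0.999907. At an unadjusted p under 0.05 there were 170 (67 higher, 103 lower), where chance gives 1126, and the 23 candidates (10 higher, 13 lower) compare with 225 expected from the p alone. Groups did not overlap at 3893 probe sets, or 17.3%, where chance gives 33.3%. With only the brightest 25% of probe sets tested, 1 passed, and it was Pck1 (limma, adjusted p = 0.00714). Its log2 difference was −2.77 as in the main fit, where its unadjusted p by limma was 0.0048. Fewer tests alone would not give that adjusted p, and the variance prior was estimated anew on the probe sets tested. Leaving out the array labelled knockout 2 gave 56 higher and 184 lower, and leaving out knockout 1 gave 17 higher and 7 lower, but after quantile normalization the fit without knockout 2 gave 0 in both directions. The differences themselves stayed as large, with Klrd1 at −4.02 before and −4.07 after (standard errors 0.53 and 1.13) and Lct at −5.23 and −5.30 (0.86 and 0.94), and the median standard error went from 0.61 to 0.38. The prior degrees of freedom, by which limma shares information between probe sets, went from no finite value to 4.10. In a test chosen after seeing the data, a prior of 4.10 on the deposited values gave 0 calls, and no finite limit on the quantile-normalized values gave 1216 higher and 1452 lower, so the number of calls turned on that prior.

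Gene groups of absorptive enterocytes had lower values on the arrays labelled knockout, labels that Ap1m2 did not bear out for knockout 2 and heterozygous 2. All 16 measured brush border digestive enzymes were lower (median log2 difference −0.77), among them enteropeptidase, Tmprss15, at 24.0 ± 1.97 against 11.3 ± 9.55, and neprilysin, Mme, at 129 ± 45.4 against 67.1 ± 58.3 (SD, n = 2 each). Of xenobiotic metabolism genes 27 of 28 were lower (median −0.62), with Cyp3a11 at 524, 342, 38.4 and 401 and Cyp3a25 at 297, 150, 13.3 and 243 on heterozygous 1, heterozygous 2, knockout 1 and knockout 2. Nutrient and ion transport was lower at 23 of 27 genes (median −0.42), with Slc6a20a at 169, 140, 23.0 and 138 and the water channel gene Aqp8 at 17.1, 11.4, 3.17 and 9.08. Lipid absorption was lower at 22 of 24 (median −0.27), with the fatty acid transporter gene Cd36 at 12.8, 8.05, 1.60 and 7.67 and the sterol exporter gene Abcg8 at 32.3, 29.1, 6.84 and 32.6.

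After quantile normalization the lowest array for each of these 4 lists was knockout 1, and knockout 2 lay above heterozygous 2 at 13 of 16 digestive enzymes, 22 of 28 xenobiotic genes and 19 of 27 transport genes but at 10 of 24 lipid absorption genes. With 1 array left out, the medians ranged from −1.59 to −0.040 for digestive enzymes, −1.21 to −0.16 for xenobiotic genes, −0.69 to −0.12 for transport, −0.42 to −0.16 for lipid absorption, −0.54 to −0.0065 for the proximal list, −0.86 to −0.20 for the distal list and −0.39 to −0.17 for brush border structure. The value nearest 0 came without knockout 1 for each of these except lipid absorption, where it came without knockout 2. None of these 7 lists passed without knockout 1, and without heterozygous 1 only transport and the proximal list did. Camera with its preset correlation placed the first 4 below other genes, with adjusted p of 1.2e-10, 8.5e-12, 4.3e-08 and 9.9e-05 in that order, but none held with the correlation estimated from the arrays (adjusted p = 0.56 with an estimated correlation for each). The proximal small intestine list was lower at 13 of 14 genes (median −0.24, adjusted p = 0.00097), with lactase, Lct, at 312, 82.3, 3.97 and 237, and the distal list at 6 of 7 (median −0.50, adjusted p = 0.033). Brush border structure was lower at 17 of 19 (median −0.24, adjusted p = 0.0039), with the scaffold gene Pdzk1 at 69.8, 29.7, 2.32 and 61.9. PPAR-alpha targets were lower at 18 of 19 (median −0.19, adjusted p = 0.00064), with Pdk4 at 30.9 ± 5.25 against 11.4 ± 8.37 and Angptl4 at 20.9 ± 5.95 against 8.97 ± 1.88 (SD, n = 2 each). Without heterozygous 2 the PPAR-alpha median was 0.063 and without knockout 2 it was 0.050. Each of these 4 lists also had an adjusted p = 0.56 with an estimated correlation. Villus tip markers were lower at 9 of 13 and did not pass (adjusted p = 0.16).

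Proliferation genes had higher values on the arrays labelled knockout at all 36 kept members (median log2 difference 0.51, preset camera adjusted p = 2.8e-11, but adjusted p = 0.56 with an estimated correlation). All 36 were highest on the array labelled knockout 1, and without that array the median was −0.22, against 0.25 to 1.28 without 1 of the others. Birc5, the mitotic regulator survivin, had 7.02, 15.3, 48.4 and 10.1 on heterozygous 1, heterozygous 2, knockout 1 and knockout 2, and Aurkb, a mitotic kinase, had 2.43, 4.39, 10.5 and 3.51. Wnt/beta-catenin targets (12 of 19 higher, adjusted p = 0.17) and crypt stem cell markers (11 of 13 higher, adjusted p = 0.12) did not pass. Both did without heterozygous 1 (medians 0.12 and 0.12, adjusted p = 0.0035 and 0.0017), and with each array left out their medians ranged from 0.037 to 0.34 and from 0.059 to 0.39. The stem cell factor gene Ascl2 had 2.23, 0.33, 2.20 and 2.53, and Cdca7 had 5.59, 8.23, 10.3 and 9.83.

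Of the groups tied to the function of AP-1B, the adaptor, basolateral sorting and junction lists did not pass in the labelled comparison, and each turned sign with 1 array left out. Their medians then ranged from −0.30 to 0.29, −0.29 to 0.25 and −0.37 to 0.38 in that order. These are medians of deposited values, and the turn in sign was not particular to these lists, since oxidative phosphorylation ranged from −0.19 to 0.17. Clathrin adaptor subunits had a median log2 difference of −0.019 over 29 genes (17 lower, adjusted p = 0.62), and Ap1s3, another AP-1 subunit, had 31.7, 26.1, 18.9 and 8.61 on the 4 arrays in the order above. The basolateral sorting list had a median of −0.0085 over 31 genes (adjusted p = 0.94), and that median was positive under quantile normalization. In it, Pigr, the receptor that carries polymeric immunoglobulin across the epithelium, had 495, 382, 296 and 418, and the transferrin receptor gene Tfrc had 20.9, 107, 163 and 35.5. The polarity and junction list had a median of 0.026 over 33 genes (adjusted p = 0.95), which turned negative with median centring, and Cldn2, a pore-forming claudin, had 14.4, 115, 171 and 29.9. Lysosome genes were lower at 22 of 25 (median −0.27, adjusted p = 0.0072, but adjusted p = 0.70 with an estimated correlation), with Ctss at 116, 112, 68.1 and 97.3. Their median was 0.18 without heterozygous 2, −0.018 without knockout 2 and −0.64 without heterozygous 1.

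Markers of other cell types, which EDTA-isolated epithelium can hold, were also compared by label, with the same reserve over the labels of heterozygous 2 and knockout 2. The labelled groups did not overlap at only 2 of 18 T cell genes and 0 of 18 myeloid genes. After quantile normalization, knockout 2 lay above heterozygous 2 at 15 of 18 and 16 of 18 in that order. T cell markers were lower at 17 of 18 genes (median −0.90, adjusted p = 2.0e-09) and myeloid markers at 16 of 18 (median −0.56, adjusted p = 1.8e-05), each with an adjusted p = 0.56 with an estimated correlation. Without knockout 1 the T cell median was 0.31 (adjusted p = 8.4e-05) and the myeloid median 0.10, without heterozygous 1 they were −0.18 and 0.0089, and without heterozygous 2 or knockout 2 they were −2.04 or −2.30 and −1.24 or −1.12. Granzyme A, Gzma, had 244, 53.8, 5.79 and 149, Ccl5 had 93.2, 13.3, 2.01 and 61.8, the natural killer receptor gene Klrd1 had 17.4, 3.09, 0.160 and 8.68, and Fcer1g had 8.33, 2.66, 0.107 and 4.92 on heterozygous 1, heterozygous 2, knockout 1 and knockout 2. Lyz2 had 42.0, 18.1, 20.8 and 15.6, lowest on knockout 2, and the macrophage receptor gene Csf1r had 22.7, 3.26, 3.89 and 8.19, lowest on heterozygous 2. B and plasma cell markers (8 of 14 lower, adjusted p = 0.12) did not pass, with the immunoglobulin J chain gene Jchain at 205, 34.9, 34.1 and 39.6 and Igha at 413, 204, 237 and 199. Their median was −0.57 without heterozygous 2 (adjusted p = 0.00013), −0.52 without knockout 2 (adjusted p = 0.0055), 0.25 without knockout 1 (adjusted p = 0.19) and 0.060 without heterozygous 1 (adjusted p = 0.15). The stromal and muscle list did not pass either (adjusted p = 0.34), and its median (−0.11) and mean (0.090) differed in sign, but without heterozygous 1 the median was 0.23 (adjusted p = 0.0080). Its smooth muscle genes Actg2 (0.962 ± 0.0134 against 2.25 ± 0.471) and Myh11 (0.599 ± 0.00424 against 1.51 ± 0.0863; SD, n = 2 each) had higher values on both arrays labelled knockout.

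Pancreatic acinar markers were higher at 13 of 15 genes (median 0.62, adjusted p = 2.3e-05, but adjusted p = 0.56 with an estimated correlation). After quantile normalization, 12 of the 15 were highest on the array labelled knockout 2. Carboxypeptidase A1, Cpa1, had deposited values of 0.079, 0.166, 0.089 and 8.89 on the 4 arrays, and Cpb1 had 0.054, 1.55, 0.569 and 6.34. On the deposited values the bright members Zg16 (631, 498, 556 and 459) and Cela1 (8.63, 21.8, 27.7 and 19.8) were not highest on knockout 2. The list's median log2 difference was −0.24 without knockout 2, 0.34 without heterozygous 1, 1.41 without heterozygous 2 and 1.89 without knockout 1.

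Of the defence and interferon groups, interferon-stimulated genes were lower at 20 of 23 (median −0.39, adjusted p = 0.00023, but adjusted p = 0.56 with an estimated correlation), with Oasl2 at 25.7, 29.8, 11.9 and 18.4. Their median ranged from −0.80 without knockout 2 to −0.14 without knockout 1, and after quantile normalization it lay lowest, at −0.75 from the 4-array mean, on knockout 1, where the T cell and myeloid medians were also lowest. Mucosal defence genes (10 of 16 lower, adjusted p = 0.30), NF-kappaB and cytokine genes (11 of 14 lower, adjusted p = 0.097) and MHC class II genes (4 of 8 lower, adjusted p = 0.60) did not pass. Mucosal defence had a median of −0.31 without knockout 2 (adjusted p = 0.019), and 0.042 and 0.069 without knockout 1 and heterozygous 2. The MHC class II median was 1.55 without knockout 1 (adjusted p = 5.5e-10), 0.73 without heterozygous 1 (adjusted p = 0.00039), −0.73 without heterozygous 2 (adjusted p = 0.00013) and −1.43 without knockout 2 (adjusted p = 1.6e-05). The antimicrobial lectin genes Reg3b and Reg3g had 63.5, 152, 39.8 and 211, and 24.4, 82.1, 21.9 and 69.1, on heterozygous 1, heterozygous 2, knockout 1 and knockout 2.

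Among secretory lineages, enteroendocrine markers were lower at 15 of 19 (median −0.38, adjusted p = 0.0013, but adjusted p = 0.56 with an estimated correlation), with neurotensin, Nts, at 2.34 ± 0.236 against 1.02 ± 0.00849 (SD, n = 2 each). Of the fits with 1 array left out, the enteroendocrine list passed in that without heterozygous 2 alone, with medians from −0.41 to −0.26. Tuft cell markers were lower at 10 of 13 (median −0.29, adjusted p = 0.026, but adjusted p = 0.65 with an estimated correlation), and their median was 0.10 without heterozygous 1, 0.13 without knockout 1 and −0.67 without heterozygous 2. Goblet cell markers (13 of 20 lower, adjusted p = 0.17) and Paneth cell markers (6 of 7 lower, adjusted p = 0.067) did not pass, with the Paneth lysozyme gene Lyz1 at 512, 248, 381 and 150. The Paneth median was −0.94 without knockout 1 (adjusted p = 8.4e-05), −0.88 without heterozygous 2 (adjusted p = 0.00013), 0.089 without heterozygous 1 and 0.073 without knockout 2. The goblet median was −0.42 without knockout 1 (adjusted p = 0.024), −0.32 without heterozygous 1, 0.055 without heterozygous 2 and 0.048 without knockout 2. Cholesterol biosynthesis (9 of 20 lower, adjusted p = 0.94), the unfolded protein response (8 of 23, 0.62), immediate early genes (12 of 22, 0.77), the circadian clock (11 of 18, 0.51) and oxidative phosphorylation (14 of 28, 0.95) did not pass, the bracketed values being adjusted p. The cholesterol median was −0.87 without knockout 1 (adjusted p = 5.5e-10), −0.69 without heterozygous 1 (adjusted p = 1.8e-05), 0.76 without heterozygous 2 (adjusted p = 0.00081) and 0.94 without knockout 2 (adjusted p = 0.0017). Immediate early genes had −0.36 without knockout 1 (adjusted p = 0.0079) and 0.38 without knockout 2 (adjusted p = 0.21).

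**Figure D3:**
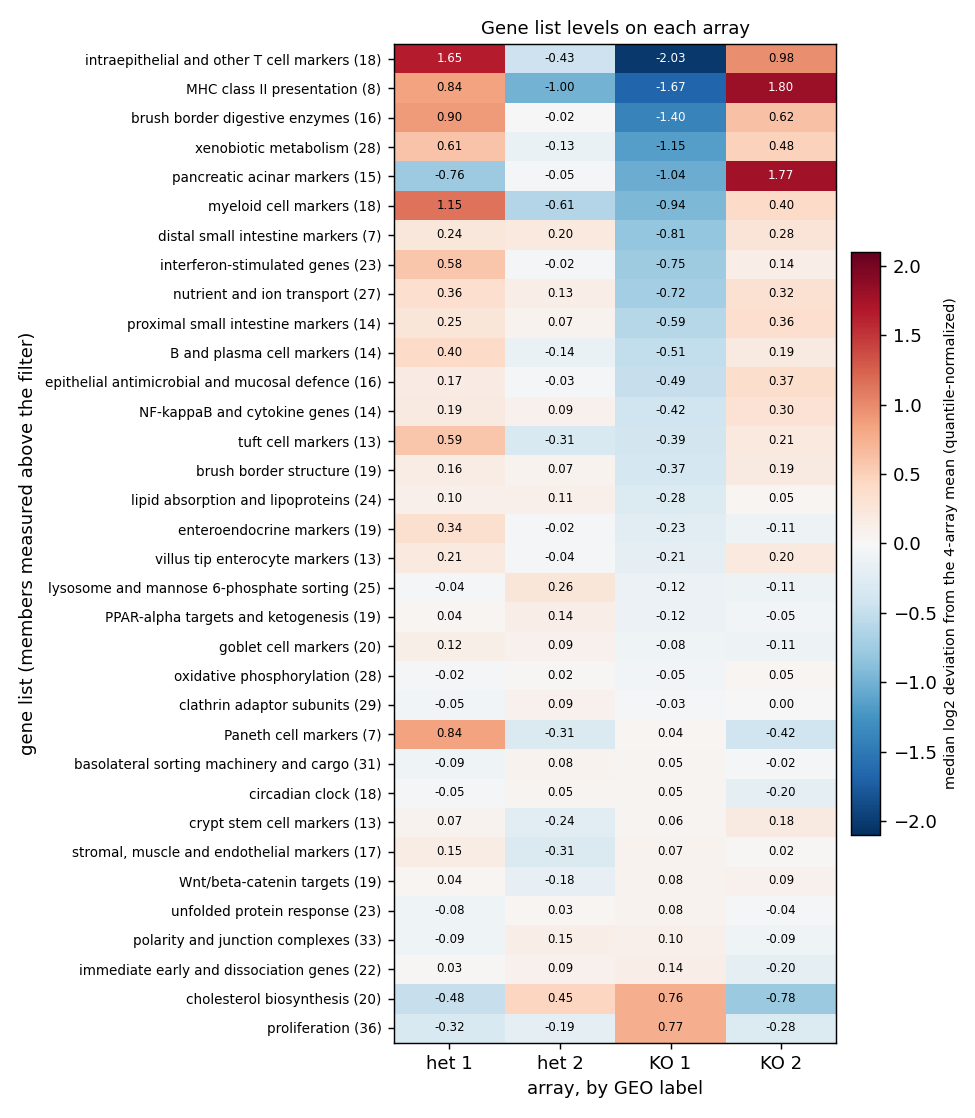
Median log2 deviation from the 4-array mean over each tested list's members, by array, after quantile normalization (red, higher; blue, lower; number of members in brackets). T cell markers read 1.65, −0.43, −2.03 and 0.98 and proliferation genes −0.32, −0.19, 0.77 and −0.28 on heterozygous 1, heterozygous 2, knockout 1 and knockout 2.

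In all, 16 of the 34 lists passed with the preset correlation (14 lower, 2 higher) and 14 of these also did after quantile normalization, while 0 passed with an estimated correlation (lowest unadjusted p 0.0806) and 0 with fry (lowest adjusted p = 0.93). Of 657 list members, 8 had an unadjusted p under 0.05 and 0 passed by limma, both over all probe sets and adjusted over the list alone. The estimated inter-gene correlations ranged from −0.056 to 0.96 with a median of 0.32, and for 10 of the 16 lists knockout 1 was the extreme array. None of the 16 kept its sign and its side of the threshold with each array left out in turn. Without knockout 1, 8 lists passed, 5 of them outside the 16, and of the 16 only 2 kept both while 4 had a median of the other sign.

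The genes next to Ap1m2 were compared to look for a passenger segment around the targeted locus. Among 77 kept probe sets of the 100 nearest genes, 0 were candidates by limma (0.079 expected) and 1 had an unadjusted p under 0.05 (0.58 expected). Camera gave an unadjusted p of 0.79 for them, and 0.95 with an estimated correlation. Since only 0.079 candidates were expected, and 0.147% of simulated 4-fold changes were called with the real residuals, a count of 0 decides nothing. The comparison also followed the labels, which the Ap1m2 signal went against for heterozygous 2 and knockout 2.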

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

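The comparison by label was planned, and the other splits and the tests of explanations in this part were chosen after the results were seen. Ap1m2 differed between the labelled genotypes in opposite directions at the 2 replicate numbers. The log2 difference, knockout minus heterozygous by label, was −2.85 for the replicate 1 arrays and 2.28 for the replicate 2 arrays, with 1 array on each side, and the difference between them was not tested.

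Ap1m2 divided across the genotype labels and the whole arrays did so in part, heterozygous 2 lying 2-fold or more from knockout 1 at 2151 probe sets and from knockout 2 at 2509 (1860 and 1699 after quantile normalization). Of the 3 ways to split the arrays into pairs, the labels gave 0 probe sets past the adjusted threshold by limma (170 at an unadjusted p under 0.05), the replicate numbers gave 7 (194), and the split of heterozygous 1 and knockout 2 from heterozygous 2 and knockout 1 gave 805 (7578), which points to a structure of the samples. Unequal scaling does not account for all of this, since the third split still gave 138 after quantile normalization, against 0 for each of the others. The 7 calls by replicate number were probe sets of the sex-linked Xist and Eif2s3y, probe sets not named for 1 gene, and the pancreatic gene Prss2. Those not named for 1 gene were lower on the replicate 2 arrays, with log2 differences of −5.29, −3.52 and −4.26 against −5.23 for Eif2s3y. Prss2 had a log2 difference of 3.99, replicate 2 minus replicate 1 (limma adjusted p = 0.029). An exchange of the genotype labels between the 2 replicate 2 arrays is a candidate explanation raised by the Ap1m2 difference itself, 2.28 on the log2 scale between those arrays, so that value is no separate test of it. A day or batch shared by the crossed pairs cannot be told apart from an exchange, because the deviations of those pairs correlated at 0.51 and no label gives a date, and a genotype effect that runs in opposite directions in the sexes also stays open, untested.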

How the results depend on the processing

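The crossed block and the 3 estimated-correlation settings other than the planned one were chosen after seeing the data; the other settings were planned. For calls by limma, the counts of 0 higher and 0 lower held under every setting that kept 4 arrays except the brightest 25%, with 1 lower. Without each array in turn, the higher calls ranged from 0 to 56 and the lower from 0 to 184, the upper ends without knockout 2; these fits assume that the lone array varies like the other group. Candidates, 23 in the main setting, numbered 196 with no filter, 13 in the brightest 25%, 5 with median centring, 13 with quantile normalization (8 higher, 5 lower) and 14 with cyclic loess, and 31 to 704 with 1 array left out. These scalings moved array medians by up to 0.22 in size on the log2 scale, in opposite directions within each label. The cause was not tested. Ap1m2 differed by −1.79 (without knockout 2) to 1.22 (without knockout 1), and by 0.78 without heterozygous 1, which follows from dropping 1 of 4 unlike values. Gene lists past the threshold numbered 16, 8 to 19 with 1 array left out, and 0 with fry, with an estimated correlation, and with it after quantile normalization, without knockout 1 or without knockout 2. Median log2 differences with 1 array left out ranged from −0.87 to 0.94 for cholesterol biosynthesis, −0.49 to 0.063 for PPAR-alpha targets, −0.22 to 1.28 for proliferation, −1.43 to 1.55 for MHC class II, −0.67 to 0.13 for tuft cells, −2.30 to 0.31 for T cells, −1.24 to 0.10 for myeloid cells, −0.17 to 0.23 for the stromal list, −0.24 to 1.89 for pancreatic markers and −0.64 to 0.18 for lysosome genes. With an estimated correlation and knockout 1 left out, proliferation had −0.22, tuft 0.13, T cell 0.31 and myeloid 0.10, and with knockout 2 left out PPAR-alpha had 0.050 and pancreatic markers −0.24. Xist ranged from −3.54 to 3.74 and Eif2s3y from −2.85 to 3.19.

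The replicate number was also fitted as a block. Arrays of the same number deviated from their group means in opposite directions (correlation −0.51), which with 2 arrays a group is the mirror of the 0.51 of the crossed pairs. The numbers coincide with sex by Xist and the Y-linked transcripts, and the labels tie them to nothing else. The block gave 0 calls, 28 candidates and 16 lists. With the crossed pairs as a block instead, there were 0 calls, 131 candidates and 1 candidate among the neighbours of Ap1m2.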

Other observations

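The stromal and scaling tests in this part were chosen after their results were seen, and the second marker lists were set after the patterns but before their own values were looked at, leaving out genes already seen. Of the genes named, Hmgcs1, Sqle, Cyp51, Cd74, H2-Aa, Cela2a, Cela3b, Prss2, Cd52, Rac2 and Bcl11b were chosen after their values were seen. Cholesterol biosynthesis genes differed widely between arrays of one label. Hmgcs1, which makes the precursor of mevalonate, had 75.1, 178, 237 and 52.7 on heterozygous 1, heterozygous 2, knockout 1 and knockout 2, the squalene epoxidase gene Sqle had 6.34, 42.9, 52.0 and 5.82, and Cyp51 had 9.90, 54.5, 60.3 and 6.58. The list's median log2 deviations from the 4-array mean after quantile normalization were −0.48, 0.45, 0.76 and −0.78, and its estimated inter-gene correlation was 0.95. Gsn, which encodes the actin-severing protein gelsolin, had 8.54, 87.5, 77.2 and 6.84.

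Antigen presentation genes also spread widely within each label. Cd74, the MHC class II invariant chain, had 57.8, 12.9, 6.82 and 109, and H2-Aa had 58.5, 15.5, 7.33 and 86.6. The regenerating protein gene Reg1 had 592, 247, 75.4 and 513.

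Most T cell, myeloid and MHC class II transcripts were lowest on the array labelled knockout 1 after quantile normalization (17 of 18, 13 of 18 and 7 of 8). A fall of equal size in every non-epithelial cell type on that array is argued against. The 6 stromal genes with a mean signal of at least 2, leaving out the bright Gsn and Mylk, lay at a median of −0.41 relative to heterozygous 1 (quartiles −0.79 and −0.22, lowest −1.15, and −0.24 over all members). At that level 14 T cell genes lay at −3.96 (quartiles −5.23 and −3.23). Since 5 of those 6 stromal genes were also lower on knockout 1, a smaller fall in stromal cells stays open. Fewer lymphocytes in that preparation may account for the T cell part: in a second list of lymphocyte genes, sharing 0 members with the other lists, 87.5% (14 of 16 kept) were lower there than on heterozygous 1, against 48.3% of all genes, with a median of −2.25. Its bright members Cd52 (14.4, 3.26, 1.61 and 12.4) and Rac2 (9.61, 3.35, 1.67 and 5.86) followed the order of Gzma, while Bcl11b (7.31, 8.86, 12.9 and 6.17) did not. Knockout 1 and heterozygous 1 both had the male pattern of sex-linked transcripts, so a difference in sex does not account for the gap between them. Whether genotype or the isolation set the number of lymphocytes on knockout 1 stays open, and heterozygous 2, with Gzma at 53.8, also lay below heterozygous 1.

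After quantile normalization, most pancreatic transcripts (12 of 15) were highest on the array labelled knockout 2. Heterozygous 2 also lay above heterozygous 1 at 9 of 15 (median 0.65) on that scale. Scaling is argued against, since the list's median deviation on knockout 2 was 1.77 after quantile normalization. Pancreatic tissue carried over with the intestine is a candidate explanation that stays open, since a second list of pancreatic genes had 4 kept members, too few to decide, of which 25% (1) were highest there. On the deposited values, the brightest of the first list's members that were highest on knockout 2 were Cela2a (0.120, 3.49, 0.082 and 24.5), Cela3b (0.563, 4.48, 1.21 and 17.4) and Prss2 (0.227, 4.83, 0.179 and 13.0). Each was next highest on heterozygous 2, so the excess was not confined to knockout 2. Of the 15, 1 is also in the goblet cell list and 6 were above 1 on all arrays, and no biological explanation was tested.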
